A study of Mus musculus with 6 samples.

How the data were processed

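The samples were 6 single-cell libraries labelled as mouse spleen, 2 per protocol, made with the 10x Genomics 3′ kit v3.1, the 5′ kit v2 and the 5′ kit v2 with added dNTP and longer extension times, per the labels' protocols. The cDNA was not fragmented and was sequenced on R10.4.1 flow cells of a PromethION instrument with the V14 ligation chemistry, per the labels' protocols. The labels' protocols describe spleens passed through a strainer and treated with a red cell lysis buffer for the replicate 1 libraries. For the replicate 2 libraries they describe collagenase isolation of pancreatic islets and depletion of insulin cDNA with Cas9, although the tissue label is spleen. The series text speaks of 3 islet libraries, 1 of them sequenced with short reads, which conflicts with the labels of the 6 samples analysed here. Libraries were therefore used as labelled, and pancreas markers were counted in each.

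The authors deposited, for each library, a matrix of raw counts per gene symbol and cell barcode, with whole numbers and no normalization. The build mm10 is named per the submitters' processing notes, which name Seurat, without a role or version, for the replicate 2 samples. The long-read aligner, the gene annotation, the use of strand, the rule that called cells and whether the counts were collapsed by molecular identifier are not given in the sources used here, so the values are called counts. The smallest number of genes per barcode was 4 and 10 in the 3′ libraries, below the floor used here. Because the counts are per gene, the tests of transcripts and transcript usage that had been planned were not run. Depth ranged from 723341 to 2627253 counts per library and from 332 to 606 counts per kept cell in the median. Intervals and floors for counts of 0 (3 counts) cover counting error only.

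Cells with at least 200 genes and at most 20% mitochondrial counts were kept. Of the barcodes in replicates 1 and 2, 417 and 919 (3′), 1671 and 540 (standard 5′) and 562 and 348 (modified 5′) had fewer genes. Scrublet with an expected rate of 0.05 marked 14, 0, 4, 2, 11 and 5 cells in the same order of libraries, at most 0.601%, which is too few to count as a working doublet filter. The marked cells were removed, but doublets remain. Each library was clustered separately, so that the protocol could not shape the clusters, with scanpy 1.11.5 under Python 3.11.15. Counts were scaled to 1000 per cell and log-transformed, 2000 variable genes were chosen among genes seen in at least 3 cells, without receptor variable segments and haemoglobin genes, and 30 principal components, 15 neighbours and Leiden resolution 0.5 were used. A cluster was called after a cell type only where at least 3 of that type's markers were among its top 50 genes by fold (50 CPM added, genes in at least 10% of its cells) and its leading 10 genes did not point to another type. Otherwise it stayed unnamed. Tests within a class required at least 50 cells in every library, which B-like (405 or more) and T-like cells (346 or more) met and NK-like cells (19 in standard 5′ replicate 1) did not.

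Counts were summed over kept cells per library and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM factors, filterByExpr, all 6 libraries in 1 fit, the group as the only term and Benjamini-Hochberg adjustment at 0.05. The labels' extraction text differs between replicates 1 and 2 and is shared by the 3 libraries of each number, and libraries of the same number deviated together (correlations of deviations from the group means 0.616, 0.507 and 0.421 over 6843 genes). The number is therefore read as a batch, and the fit with it as a block is given where it changes a call or moves a count by over 1.5 times. That reading was made after the calls of the block fit had been seen, and the labels do not say that libraries of 1 number share an animal or day. TMM factors were 1.17 and 1.21 for 3′, 0.895 and 0.919 for standard 5′ and 0.911 and 0.944 for modified 5′, and the common biological coefficient of variation was 0.235. The residual degrees of freedom were 3. Printed folds are log2 fold changes with standard errors from that fit, printed CPM values are counts of kept cells scaled to the library total, and folds within 1 replicate add 1 CPM to both values. The fit was tested on simulated counts drawn from the means and library sizes of these data, with 200 genes of at least 20 CPM changed by log2 values of 1 or 2. Library pairs were compared for duplication by a chi-square of their counts. The smallest value per degree of freedom was 4.68, so no library pair agreed within sampling noise.

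The named genes follow a rule fixed before the data were examined, as were the tests, the gene lists and most of the alternatives. For each comparison over all cells the rule takes the 10 largest rises and the 10 largest falls among genes that passed, with a mean of at least 50 CPM over the 6 libraries, every library of a group above every library of the other, and a symbol that is not a numbered gene model, clone or pseudogene. It adds up to 4 members per list with the smallest p, and takes 5 rises and 5 falls within B-like and T-like cells. Where fewer than 5 genes pass, the 10 smallest p are given as values. The rule was met by 1303 genes for standard 5′ against 3′, 1082 for modified 5′ against 3′ and 0 for modified against standard 5′. Some genes that met the rule are not reported here, and genes named outside it were chosen after their values were seen.

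In all, 28 gene lists were fixed, and 24 had at least 3 tested members. They cover markers of B, T and NK cells, monocytes or macrophages, neutrophils, dendritic, plasma, erythroid, stromal or endothelial and pancreas cells and platelets, and ribosomal, mitochondrial, nuclear noncoding, histone, immediate early, heat shock, interferon, MHC, immunoglobulin, T cell receptor, oxidative phosphorylation, proteasome, cell cycle, splicing and lymphocyte isoform genes. No pancreas gene was tested and no mitochondrial rRNA was analysed here. Lists were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all lists and the 3 comparisons. No list test took transcript length into account. The alternatives were an estimated correlation, under which no list passed, and fry, which asks only whether a list's genes move on balance in 1 direction.

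Detection was compared after thinning without replacement. The plan was 1000 counts per cell, but under 50% of the cells of each library reached that depth, so 500 was used, as the plan provided, and each library was also thinned to 365826 counts, the smallest kept total. Library values were compared by exact two-sided permutation tests of 2 against 2, whose smallest p is 0.33, so no such test could reach 0.05. Of 20279 gene symbols, 19900 (98.1%) matched 1 gene of GENCODE M21 on GRCm38, the build of mm10, 343 were not found and 36 were shared by several genes. Length is that of the longest annotated transcript. Shared sequence was measured as the percentage of the 31-mers in the first or last 500 nt of a gene's longest transcript that occur in another gene.

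The alternatives were relative log expression size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, all deposited barcodes, libraries thinned to the smallest total, Leiden resolution 1.0, doublets kept, other depths and length definitions, and each library left out in turn. Where a left-out library leaves its group with 1 library, that library is assumed to vary like the other groups. Added after the data were seen were fits without haemoglobin genes, detection in B-like and T-like cells and over all barcodes at 200 counts, detection per library and length in B-like cells, lists within B-like and T-like cells, and a test of the difference between the effects in B-like and T-like cells. That test used the counts of both classes in 1 edgeR fit with library as a term, over 9280 genes. The level of its genes and of Igha in each class and library, and the share of cells with a count, were also taken after the data were seen. Y-linked expression was not analysed here.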

Results

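Single cells labelled as mouse spleen were profiled by Nanopore long-read sequencing after 3 ways of making barcoded cDNA on a droplet platform. In the 3′ kit the cell barcode is joined at the poly(A) end of each transcript, and in the 5′ kit it is joined at the template-switch end. The modified 5′ protocol added 1 µl of 10 mM dNTP at reverse transcription and at cDNA amplification. It used a reverse transcription extension of 2 h in place of 45 min and an amplification extension of 3 min in place of 1 min. Each protocol had 2 libraries, called replicates 1 and 2. All 6 were labelled as spleen of female mice aged 10 weeks, and the series text gives the inbred strain C57BL/6. The extraction text of the 3 replicate 2 libraries describes pancreatic islets and the removal of insulin cDNA, which conflicts with their spleen label and splits the libraries by replicate number. The labels do not say that replicates came from separate animals, so the p-values measure the spread between libraries, which may be technical.

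The deposited tables held raw counts per gene and barcode. Total counts in replicates 1 and 2 were 1944993 and 2627253 for 3′, 723341 and 2027581 for standard 5′, and 1570654 and 2161929 for modified 5′. After filtering, 2331 and 4045 cells were kept for 3′, 861 and 3208 for standard 5′, and 2022 and 3111 for modified 5′. Standard 5′ replicate 1 stood apart, with 34.0% of its barcodes kept against 78.3% to 89.9% in the other libraries and a median of 332 counts per kept cell against 482.5 to 606. Haemoglobin transcripts, which mark red cells, took 13.4%, 15.7% and 22.3% of all counts in the 3′, standard 5′ and modified 5′ replicate 1 libraries, and 0.319%, 0.403% and 0.524% in the replicate 2 libraries.

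B-like and T-like cells made up most of every library. B-like cells were 57.9% ± 1.44 of the cells left after doublet removal in 3′, 52.4% ± 7.21 in standard 5′ and 59.3% ± 0.658 in modified 5′ (mean ± SD, n = 2 libraries). T-like cells were 28.5% ± 1.20, 36.5% ± 5.54 and 29.7% ± 3.43. The shares in single libraries ranged for B-like cells from 47.3% (95% exact interval 43.9% to 50.7%) in standard 5′ replicate 1 to 59.8% (58.0% to 61.5%) in modified 5′ replicate 2. For T-like cells they ranged from 27.3% (25.7% to 28.9%) in modified 5′ replicate 2 to 40.4% (37.1% to 43.8%) in standard 5′ replicate 1. NK-like cells took 5.14% and 5.71% of the 3′ cells, 2.22% and 3.18% of the standard 5′ cells, and 2.49% and 6.18% of the modified 5′ cells. Monocyte-like or macrophage-like clusters held 6.01%, 5.02% and 4.48% of the cells of the 3 replicate 2 libraries and 3.85% in standard 5′ replicate 1. None was found in the 3′ and modified 5′ replicate 1 libraries, where unnamed clusters held 3.41% and 5.07% of cells. Erythroid-like clusters held 4.96%, 6.30% and 1.49% of the 3′, standard 5′ and modified 5′ replicate 1 cells, and 0%, 1.25% and 1.03% of the replicate 2 cells. The 0% in 3′ replicate 2 is not absence, since an unnamed cluster of 54 cells there (1.335%), led by Hist1h1b, Car1 and Ube2c, had 2 erythroid markers among its top 50 genes where 3 were needed for a name. Plasma-like cells formed a cluster in the 3′ (0.791%) and standard 5′ (0.561%) replicate 2 libraries, and an unnamed cluster of 40 cells (1.29%) in modified 5′ replicate 2 was led by Jchain and Igha. No cluster of neutrophil-like, dendritic-like, platelet-like, stromal-like or pancreas-like cells formed in any library, although such cells can lie within other clusters. These smaller classes moved with the clustering. At Leiden resolution 1.0 in place of 0.5, NK-like cells were 5.265% and 2.497% of 3′, 4.90% and 3.24% of standard 5′ and 6.71% and 3.25% of modified 5′ cells. In modified 5′ replicate 1, 2 clusters named erythroid-like then held 4.82%, but 67 of those 97 cells lay in a mixed cluster led by Lyz2, Ifitm3, Hbb-bt and Cst3, with 6 erythroid markers and 6 of another class among its top 50 genes, and the other 30 were as many as the 1.49% above. A plasma-like cluster there held 2.19%, and in modified 5′ replicate 2 a dendritic-like cluster held 2.54% and monocyte-like or macrophage-like cells 2.00%. The B-like share was 6.94 points higher in modified than in standard 5′ (within replicates 1 and 2, 11.57 and 2.31 points; exact two-sided permutation p = 0.33). The T-like share differed by -6.76 points (-8.25 and -5.26, exact p = 0.33), and the smallest p that 2 libraries against 2 can give is 0.33. Against 3′, the standard 5′ share was -5.50 points for B-like cells (-11.61 and 0.61, exact p = 0.67) and 7.98 points for T-like cells (12.75 and 3.21, exact p = 0.33). The modified 5′ shares differed from 3′ by 1.44 points for B-like cells (-0.04 and 2.92, exact p = 0.67) and 1.23 points for T-like cells (4.5 and -2.05, exact p = 1). Without standard 5′ replicate 1 the B-like difference was 1.845 points between modified and standard 5′ and -0.405 between standard 5′ and 3′, and the T-like differences were -2.835 and 4.06 points. Without standard 5′ replicate 2, the B-like differences were 12.04 and -10.6 points and the T-like difference between modified and standard 5′ was -10.68, which was -4.33 without modified 5′ replicate 2. Between modified 5′ and 3′, leaving out 1 library gave 0.425 (without 3′ replicate 2) to 2.455 points (without 3′ replicate 1) for B-like and -1.2 (without modified 5′ replicate 1) to 3.65 points (without modified 5′ replicate 2) for T-like cells. At Leiden resolution 1.0 the B-like difference between modified and standard 5′ was 3.805 points (11.41 and -3.8 within replicates), and both differences between modified 5′ and 3′ turned, to -0.925 points for B-like (-0.48 and -1.37) and -2.665 points for T-like cells (0.36 and -5.69).

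The first comparison asked how gene counts differ between standard 5′ and 3′ capture. Cox4i1, which encodes a subunit of cytochrome c oxidase, rose from 146 and 102 CPM (counts scaled to the library total and its TMM factor) in 3′ to 1306 and 1356 CPM in standard 5′, a log2 fold change of 3.43 ± 0.24 (± SE, 2 libraries per group, edgeR adjusted p = 2.5e-04). Pld3, which encodes a lysosomal exonuclease, rose by 3.70 ± 0.30, from 9.94 and 5.73 to 83.0 and 110.1 CPM. Rps25, a small-subunit ribosomal protein gene, changed most in the other direction, at -4.10 ± 0.27, from 956 and 646 CPM to 43.0 and 48.6 CPM (edgeR adjusted p = 2.5e-04). Psma7, which encodes a subunit of the 20S proteasome core, changed by -2.19 ± 0.24, from 248 and 305 CPM to 64.5 and 58.2 CPM. Over 11546 genes tested, 2689 passed an adjusted p of 0.05, 1443 higher and 1246 lower in standard 5′, and 1883 of them by at least 2-fold.

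**Figure D1:**
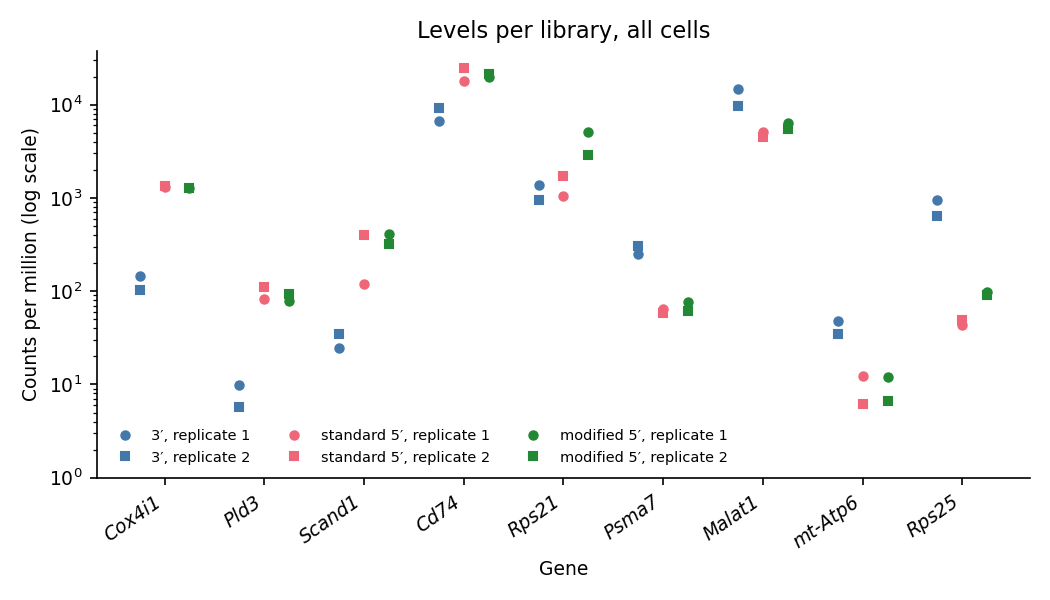
CPM of kept cells on a log axis for 9 genes, with 1 point per library, colours for the 3 protocols, circles for replicate 1 and squares for replicate 2. Cox4i1, Pld3, Scand1 and Cd74 lie higher in the 5′ libraries than in the 3′ libraries, and Psma7, Malat1, mt-Atp6 and Rps25 lie lower.

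The other rises among the 10 largest were those of Gpx4 (3.56 ± 0.29, chr 10: 80047166 to 80056439), which encodes a lipid peroxide reductase, and Atp5o (3.29 ± 0.27), a subunit gene of ATP synthase. Scand1 (3.18 ± 0.47, chr 2: 156311847 to 156312704), Anxa2 (3.16 ± 0.35, chr 9: 69453620 to 69491795), a calcium-dependent membrane-binding protein gene, and Tmem223 (3.03 ± 0.23, chr 19: 8770996 to 8772475) rose too. They also included Bcap31 (2.93 ± 0.21, chr X: 73686178 to 73716175) of the endoplasmic reticulum membrane, Selenof (2.89 ± 0.22, chr 3: 144570304 to 144597680), a selenoprotein gene, and Gnai2 (2.84 ± 0.25, chr 9: 107614125 to 107635367), an inhibitory G protein subunit gene. Cox4i1 lies at chr 8: 120668222 to 120674207, Pld3 at chr 7: 27532000 to 27553218, Rps25 at chr 9: 44407139 to 44410427 and Psma7 at chr 2: 180036374 to 180042433. All positions are on GRCm38 (mm10) with GENCODE M21 gene models. All genes named here are annotated as protein coding unless stated otherwise, apart from constant region genes of immunoglobulins and T cell receptors, and Atp5o had no single match in that annotation. The other falls among the 10 largest were those of S100a8 (-3.32 ± 0.67, chr 3: 90668978 to 90670035) and S100a9 (-2.54 ± 0.61, chr 3: 90692632 to 90695721), which encode the calprotectin subunits of neutrophils. H2-Q10 (-2.89 ± 0.29, chr 17: 35470089 to 35474563), a class Ib histocompatibility gene, and Polr2g (-2.31 ± 0.29, chr 19: 8793127 to 8798577), a subunit gene of RNA polymerase II, fell too. Vmn1r218 (-2.29 ± 0.27, chr 13: 23133155 to 23146112) and Olfr1307 (-2.19 ± 0.26, chr 2: 111930116 to 111949440) belong to the vomeronasal and olfactory receptor families. Mrtfb (-2.08 ± 0.26, chr 16: 13256481 to 13417529), a coactivator of serum response factor, and Map3k1 (-2.07 ± 0.22, chr 13: 111746428 to 111808993), a kinase gene of the JNK pathway, completed them. Within replicates 1 and 2, the log2 differences were 3.16 and 3.72 for Cox4i1, 2.94 and 4.05 for Pld3, -4.44 and -3.71 for Rps25 and -1.92 and -2.37 for Psma7. The last 500 nt of Gpx4 and Rps25 transcripts shared 93.4% and 77.2% of their 31-mers with other genes, against 0% for Cox4i1, Pld3 and Psma7. The assignment of counts to Gpx4 and Rps25 is therefore uncertain. The same holds for H2-Q10, Vmn1r218 and Olfr1307, which belong to families of similar genes.

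Genes of the energy, translation and protein turnover machinery were higher in standard 5′ as groups. Of 76 tested nuclear-encoded genes of oxidative phosphorylation, 36 rose and 0 fell (49 and 0 adjusted over the list alone), with a median log2 fold change of 0.73 (camera adjusted p = 2.8e-11, and adjusted p = 0.648 with an estimated correlation). Its members included Atp5g3 (2.23 ± 0.21, chr 2: 73908447 to 73911326), Ndufa10 (2.19 ± 0.24, chr 1: 92439010 to 92473860) and Uqcrc1 (1.62 ± 0.22), which belong to ATP synthase, complex I and complex III. Among 83 cytosolic ribosomal protein genes, 26 rose and 2 fell (33 and 2 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 4.5e-07, and adjusted p = 0.648 with an estimated correlation). Rpl29 (1.81 ± 0.20, chr 9: 106429454 to 106431568) and Rpl36a (1.77 ± 0.32, chr X: 134585654 to 134588062) rose, and such genes have pseudogene copies that can share reads. Of 38 proteasome genes, 18 rose and 2 fell (28 and 2 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 3.7e-06, and adjusted p = 0.648 with an estimated correlation). Psmb7 (2.10 ± 0.23, chr 2: 38588036 to 38644087) and Psmb3 (1.17 ± 0.20) rose, while Psma7 and Psmd6 (-1.62 ± 0.27) fell. In the cell cycle list 3 of 26 genes rose and 0 fell (3 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.017, and adjusted p = 0.858 with an estimated correlation). These were Mcm6 (1.28 ± 0.30), a subunit gene of the replicative helicase, and the tubulin genes Tuba1b (2.01 ± 0.23, chr 15: 98931425 to 98934565) and Tubb5 (1.05 ± 0.21). This list did not pass without 3′ replicate 2 (camera adjusted p = 0.322) or standard 5′ replicate 1 (0.86; from 1.09e-06 over the 6 libraries left out in turn).

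Immune gene groups moved as well. Among 20 T cell markers, 13 rose and 1 fell over all genes and adjusted over the list alone, with a median of 0.84 (camera adjusted p = 3.4e-04, and adjusted p = 0.648 with an estimated correlation). T-like cells were 36.5% of standard 5′ and 28.5% of 3′ cells. Cd3e (1.54 ± 0.21) and Cd247 (1.24 ± 0.23), which encode CD3 chains, Trac (1.47 ± 0.20) and the adaptor gene Lat (1.60 ± 0.25) rose. Of 7 T cell receptor constant genes, 3 of which are also T cell markers, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.0020, and adjusted p = 0.648 with an estimated correlation). They included Trbc2 (1.05 ± 0.24), Trbc1 (0.73 ± 0.21) and Tcrg-C4 (1.77 ± 0.55). Of 10 MHC class II genes, which serve antigen presentation to helper T cells, 5 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 0.0056, and adjusted p = 0.648 with an estimated correlation). Cd74 (1.42 ± 0.25, chr 18: 60803848 to 60812652), the invariant chain gene, rose from 6753 and 9231 to 17980 and 24920 CPM, and H2-DMb2 (1.38 ± 0.25), H2-Oa (1.28 ± 0.26) and H2-Eb1 (1.23 ± 0.26) rose too. For 14 MHC class I genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 0.0042, and adjusted p = 0.80 with an estimated correlation). These were H2-T22 (1.15 ± 0.24), H2-K1 (1.06 ± 0.25), H2-D1 (1.07 ± 0.26) and the immunoproteasome gene Psmb8 (0.81 ± 0.25). Among 24 immediate early genes, which respond within minutes to stimulation, 7 rose and 0 fell over all genes and adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.017, and adjusted p = 0.648 with an estimated correlation). They included the nuclear receptor gene Nr4a1 (2.35 ± 0.30, chr 15: 101254269 to 101274795), Zfp36 (1.38 ± 0.21), Nfkbia (1.11 ± 0.21) and Myc (1.22 ± 0.23), and the list did not pass without 3′ replicate 2 (camera adjusted p = 0.0577; from 0.00334 over the 6).

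Noncoding, mitochondrially encoded and neutrophil transcripts were lower in standard 5′. Of 5 tested noncoding RNAs retained in the nucleus, 4 fell and 0 rose over all genes and adjusted over the list alone, with a median of -1.40 (camera adjusted p = 0.0096, and adjusted p = 0.648 with an estimated correlation). Malat1 (lincRNA, chr 19: 5795690 to 5802672) changed by -1.35 ± 0.25, from 14700 and 9704 CPM to 5085 and 4485 CPM. Kcnq1ot1 (-1.55 ± 0.23, chr 7: 143203458 to 143296549), Neat1 (-1.04 ± 0.21, chr 19: 5824708 to 5845478) and Snhg11 (-1.40 ± 0.45) fell as well. Kcnq1ot1 is antisense to Kcnq1, so its counts are uncertain without stated strand use. Among 11 mitochondrially encoded mRNAs, 5 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.017, and adjusted p = 0.648 with an estimated correlation). The falls included mt-Atp6 (-2.43 ± 0.45, chr M: 7927 to 8607), mt-Co2 (-1.93 ± 0.44), mt-Nd1 (-0.81 ± 0.20) and mt-Nd6 (-0.84 ± 0.23). Of 10 neutrophil genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0054, and adjusted p = 0.648 with an estimated correlation). No library had a neutrophil-like cluster. S100a8 measured 47.7 and 122 CPM in 3′ and 0 and 10.7 CPM in standard 5′. Camp, which encodes an antimicrobial peptide, measured 32.3 and 58.0 CPM and 3.07 and 0 CPM, and Cxcr2 changed by -1.40 ± 0.25. The neutrophil list did not pass without 3′ replicate 2 (camera adjusted p = 0.0787; from 3.79e-06 over the 6 libraries left out in turn), nor the nuclear noncoding list without standard 5′ replicate 2 (0.0626; from 0.00373). S100a8 no longer passed with all barcodes or without standard 5′ replicate 2, and S100a9 no longer passed with DESeq2, with all barcodes or without 3′ replicate 2.

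No other tested list passed the camera test in this comparison. Among 14 B cell markers, 4 rose and 0 fell (5 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.461), led by the B cell receptor chain genes Cd79a (1.14 ± 0.24) and Cd79b (0.99 ± 0.25). In the NK cell list 2 of 12 rose (1 adjusted over the list alone, camera adjusted p = 0.12), Nkg7 (1.09 ± 0.29) and Klrb1c (0.73 ± 0.22). In the monocyte or macrophage list 1 of 18 rose (1 adjusted over the list alone, camera adjusted p = 0.137), Ly6c2 (1.55 ± 0.35). Of 27 interferon-stimulated genes, 5 rose and 2 fell over all genes and adjusted over the list alone (camera adjusted p = 0.124). Ly6e (1.47 ± 0.21) and Irf7 (1.23 ± 0.25) were among the rises. Of 41 splicing factor genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.349), with Sf3b4 at 2.69 ± 0.23 (chr 3: 96172332 to 96177564) and Srsf3 at -1.78 ± 0.20 (chr 17: 29032628 to 29043373). Of 15 genes with well-known lymphocyte isoforms, several of them in the other lists, 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.104). Pkm (1.34 ± 0.24), Clta (0.94 ± 0.21) and Myl6 (0.80 ± 0.20) rose. In the heat shock list 1 of 11 rose, Hspa8 (1.09 ± 0.31), and 0 adjusted over the list alone (camera adjusted p = 0.124). Of 10 immunoglobulin constant genes, 1 rose, Iglc1 (1.57 ± 0.48), and 0 adjusted over the list alone (camera adjusted p = 0.357), with a median of 0.73 and a mean of -0.02. No member passed, over all genes or adjusted over the list alone, among 12 dendritic cell (camera adjusted p = 0.719), 8 plasma cell (0.46), 11 erythroid (0.546) and 38 histone genes (0.37). With the replicate block the erythroid list passed (camera adjusted p = 0.0342), as did its members Alas2 (log2 fold change 1.54), Car1 (1.41), Klf1 (1.27) and Hba-a1 (1.54), the plasma cell gene Jchain (1.60), the dendritic cell gene Cd209a (1.26) and Hist1h1b (-2.17). Hist1h1b measured 1063 and 109.9 CPM in 3′ and 197 and 33.9 CPM in standard 5′. Pecam1, the single tested stromal or endothelial gene, fell by 0.77 on the log2 scale, and Itgb3, the single tested platelet gene, had a value of -0.09 ± 0.40 and did not pass.

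Within B-like cells, 3134 of 9345 tested genes passed, 1621 higher and 1513 lower in standard 5′, and within T-like cells 1899 of 7508 passed, 893 higher and 1006 lower. Cox4i1 rose by 3.30 ± 0.26 in B-like cells and 3.39 ± 0.25 in T-like cells, and Gpx4 by 3.59 ± 0.30 and 3.18 ± 0.30. Scand1 rose by 3.15 ± 0.31 and 3.15 ± 0.36, while Rps25 changed by -4.11 ± 0.30 and -4.25 ± 0.32 and H2-Q10 by -2.88 ± 0.30 and -3.24 ± 0.35. Slc25a39 (3.14 ± 0.32, chr 11: 102402985 to 102407946), a mitochondrial carrier gene, and Atp5o (3.30 ± 0.28) were also among the 5 largest rises in B-like cells. Olfr1307 (-2.47 ± 0.29), Klhl20 (-2.45 ± 0.30, chr 1: 161088375 to 161131511) and Ccdc167 (-2.40 ± 0.36, chr 17: 29687357 to 29717044) were among the 5 largest falls. In T-like cells the 5 largest rises included Anxa2 (3.70 ± 0.41) and Pld3 (3.58 ± 0.38), and the 5 largest falls included Polr2g (-3.14 ± 0.38) and Psma7 (-2.58 ± 0.31). Of the 12 lists that passed over all cells, 7 passed in the same direction in B-like and 9 in T-like cells. Cell cycle genes (camera adjusted p = 0.412 and 0.0601) and mitochondrially encoded mRNAs (0.0813 and 0.0604) passed in neither class, T cell markers (0.661) and T cell receptor constant genes (0.515) did not pass in B-like cells, and the neutrophil list was not tested in either.

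Of the 2689 genes, 2686 had the same sign in both replicate pairs, which a call on these favours. With the block 4127 passed, 2227 higher and 1900 lower. Simulated log2 changes of 1 and 2 in 100 genes each, drawn without a replicate effect, were recovered in 25% and 85%, with 5 false calls among 11346 unchanged genes (11148 of all simulated genes passed the count filter). The count fell to 966 without 3′ replicate 1 and to 221 (174 higher and 47 lower) without standard 5′ replicate 2. Without haemoglobin genes 1251 were higher and 1392 lower, and in B-like cells with relative log expression factors 1539 were higher and 1601 lower, so the larger direction depends on the scaling. The count was 1230 with every library thinned to 365826 counts, and DESeq2 gave 1536 genes, 962 higher and 574 lower. In B-like cells the count was 1722 and 554 without the same 2 libraries, and in T-like cells 892 and 327. Cox4i1, Pld3, Gpx4, Scand1, Nr4a1, Cd3e, Rps25 and Psma7 passed under every alternative run. Cd74, Malat1, mt-Atp6, Polr2g and Rpl36a did not pass without standard 5′ replicate 2.

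The second comparison set modified 5′ against 3′. Scand1 rose by 3.58 ± 0.48 on the log2 scale, from 24.9 and 35.1 to 406 and 319 CPM (± SE, 2 libraries per group, edgeR adjusted p = 0.0028). Pld3 rose by 3.51 ± 0.29 and Cox4i1 by 3.35 ± 0.24, to 1264 and 1263 CPM (edgeR adjusted p = 3.0e-04). Rps25 changed by -3.09 ± 0.25, to 96.8 and 91.4 CPM, and Selenok (chr 14: 29968308 to 29975662), which encodes a selenoprotein of the endoplasmic reticulum, changed by -2.22 ± 0.22. Of 11546 genes tested, 2124 passed, 1178 higher and 946 lower in modified 5′, and 1434 of them by at least 2-fold, while DESeq2 gave 1226 genes, 827 higher and 399 lower.

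The other large rises were those of Atp5o (3.20 ± 0.27), Tmem223 (3.18 ± 0.22), Gpx4 (3.15 ± 0.28), Anxa2 (2.83 ± 0.35), Gnai2 (2.72 ± 0.24) and Rpl36a (2.65 ± 0.32). Ighg3 (chr 12: 113356224 to 113361232), the constant region gene of IgG3, had the largest fitted rise, 7.18 ± 1.70. It measured 1287 CPM in modified 5′ replicate 1 and between 0.50 and 13.7 CPM in the other 5 libraries. The log2 differences of Ighg3 within replicates 1 and 2 were 9.75 and 0.80, and it no longer passed with all barcodes, without 3′ replicate 1 or without modified 5′ replicate 1. The other falls were those of H2-Q10 (-2.75 ± 0.27), Polr2g (-2.34 ± 0.26), Vmn1r218 (-2.18 ± 0.24) and Psma7 (-2.01 ± 0.23). Ptprcap (-2.0 ± 0.23, chr 19: 4153604 to 4156751), which encodes a protein associated with CD45, Srsf3 (-1.85 ± 0.20), Map3k1 (-1.84 ± 0.20) and Adam28 (-1.84 ± 0.25, chr 14: 68606027 to 68655842), a lymphocyte metalloprotease gene, fell as well. The last 500 nt of Ptprcap transcripts shared 94.7% and the first 500 nt of Srsf3 transcripts 73.0% of their 31-mers with other genes, so those assignments are uncertain.

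Of 76 genes of oxidative phosphorylation, 55 rose and 0 fell (65 and 0 adjusted over the list alone), with a median log2 fold change of 1.08 (camera adjusted p = 6.4e-22, and adjusted p = 0.648 with an estimated correlation). Atp5g3 (2.19 ± 0.21), Ndufa10 (2.08 ± 0.23) and Ndufb6 (1.68 ± 0.22) were among them. Among 83 ribosomal protein genes 40 rose and 1 fell (56 and 1 adjusted over the list alone, median 0.72, camera adjusted p = 2.9e-12, and adjusted p = 0.648 with an estimated correlation). Rpl29 rose by 1.83 ± 0.20. For 38 proteasome genes the counts were 6 and 2 (10 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 6.1e-04, and adjusted p = 0.684 with an estimated correlation). Psmb7 rose by 1.91 ± 0.22 and Psmd6 changed by -1.41 ± 0.25. T cell markers rose in 9 and fell in 1 of 20 cases, over all genes and adjusted over the list alone (median 0.57, camera adjusted p = 0.0012, and adjusted p = 0.648 with an estimated correlation). Cd3e rose by 1.23 ± 0.21, and Themis, which acts in T cell selection, changed by -0.97 ± 0.22. T-like cells were 29.7% of modified 5′ and 28.5% of 3′ cells. The T cell receptor constant list had 2 rises and 0 falls among 7 genes, over all genes and adjusted over the list alone (median 0.81, camera adjusted p = 0.0056, and adjusted p = 0.648 with an estimated correlation). They were Trac (1.15 ± 0.20) and Trbc2 (0.81 ± 0.24). MHC class II genes rose in 6 of 10 cases and 0 fell (8 and 0 adjusted over the list alone, median 0.94, camera adjusted p = 0.0017, and adjusted p = 0.648 with an estimated correlation). Cd74 rose by 1.36 ± 0.25 and H2-Aa by 1.18 ± 0.27. MHC class I genes rose in 3 of 14 and 0 fell (4 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 0.028, and adjusted p = 0.858 with an estimated correlation). The rises were those of H2-K1 (0.79 ± 0.24) and the peptide-loading genes Tap2 (0.98 ± 0.28) and Tapbp (0.79 ± 0.23). This list did not pass without 3′ replicate 1 (camera adjusted p = 0.349) or modified 5′ replicate 2 (0.0861; from 4.65e-04 over the 6 libraries left out in turn). Genes with well-known lymphocyte isoforms rose in 5 of 15 cases and 0 fell (6 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 0.028, and adjusted p = 0.648 with an estimated correlation). Pkm (1.08 ± 0.23), Myl6 (1.00 ± 0.20) and Rps24 (1.20 ± 0.27) were among them.

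Mitochondrially encoded mRNAs fell in 3 of 11 cases and 0 rose (5 and 0 adjusted over the list alone, median -0.60, camera adjusted p = 0.011, and adjusted p = 0.648 with an estimated correlation). These were mt-Atp6 (-2.21 ± 0.39), mt-Co3 (-1.63 ± 0.38) and mt-Nd1 (-0.66 ± 0.20). The nuclear noncoding RNAs Kcnq1ot1 (-1.38 ± 0.22), Neat1 (-1.14 ± 0.20) and Malat1 (-1.05 ± 0.25) fell and none of the 5 rose, over all genes and adjusted over the list alone (median -1.14, camera adjusted p = 0.010, and adjusted p = 0.648 with an estimated correlation). No other tested list passed. Immediate early genes rose in 6 of 24 cases over all genes and adjusted over the list alone (camera adjusted p = 0.058), including Nr4a1 (1.94 ± 0.29), Zfp36 (1.04 ± 0.20) and Junb (0.78 ± 0.21). B cell markers rose in 4 of 14 cases (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.104), with Cd79a at 1.13 ± 0.24 and Fcmr, an IgM receptor gene, at 0.97 ± 0.23. The immunoglobulin constant list had 2 rises among 10 over all genes and adjusted over the list alone (camera adjusted p = 0.079), Ighg3 and Iglc3 (1.85 ± 0.36). Ccl5 (1.10 ± 0.27) and Klrb1c (0.80 ± 0.21) rose in the NK cell list, 2 of 12 over all genes and adjusted over the list alone (camera adjusted p = 0.137). Splicing factor genes rose in 5 and fell in 5 of 41 cases (6 and 5 adjusted over the list alone, camera adjusted p = 0.53). Cell cycle genes rose in 2 and fell in 1 of 26 (1 and 0 adjusted over the list alone, camera adjusted p = 0.719), with Tuba1b at 1.49 ± 0.23, Tubb5 at 0.73 ± 0.20 and Ccnb2 at -2.15 ± 0.66. Interferon-stimulated genes rose in 2 and fell in 1 of 27 cases over all genes and adjusted over the list alone (camera adjusted p = 0.919). Their values were 1.31 ± 0.21 for Ly6e, 1.31 ± 0.21 for Ifi27l2a and -0.91 ± 0.21 for Slfn5. Cxcr2 (-0.95 ± 0.22) was the single neutrophil gene of 10 to pass (camera adjusted p = 0.954). For the cell cycle and interferon-stimulated lists the medians, -0.08 and -0.11, were negative while camera ranked the lists upward. No member passed in the monocyte or macrophage (camera adjusted p = 0.118), dendritic cell (0.564), plasma cell (0.546), erythroid (0.919), heat shock (0.73) and histone lists (0.485). Neither Itgb3 (0.34) nor Pecam1 (-0.49) passed over all genes, although Pecam1 passed adjusted over the list alone and with the replicate block (edgeR adjusted p = 0.0491). With that block the monocyte or macrophage (camera adjusted p = 0.0424) and immunoglobulin constant lists (0.0362) passed, as did single members of lists without a call above, among them Cd68 (log2 fold change 0.80), Jchain (1.24), Cd209a (1.26), Hsph1 (-0.94), Rhag (-1.41) and Hist1h1b (-2.24).

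In B-like cells 2792 genes passed, 1440 higher and 1352 lower in modified 5′, and in T-like cells 1480, 754 higher and 726 lower. Cox4i1 rose by 3.24 ± 0.25 and 3.43 ± 0.25 in B-like and T-like cells, Scand1 by 3.51 ± 0.30 and 3.53 ± 0.35, and Tmem223 by 2.92 ± 0.27 and 3.13 ± 0.33. Rps25 changed by -3.13 ± 0.26 and -3.35 ± 0.27, H2-Q10 by -2.54 ± 0.25 and -3.08 ± 0.31, Selenok by -2.49 ± 0.25 and -2.25 ± 0.29 and Polr2g by -2.24 ± 0.28 and -2.78 ± 0.34. Of the 10 lists that passed over all cells, 7 passed in the same direction in B-like and 8 in T-like cells. The isoform list passed in neither (camera adjusted p = 0.0899 and 0.191), T cell markers (0.479, ranked downward) and T cell receptor constant genes (0.95) did not pass in B-like cells, nor MHC class I genes (0.0866) in T-like cells. All 2124 genes had the same sign in both pairs used to call them. With the block 3820 passed, 1993 higher and 1827 lower. Simulated log2 changes of 1 and 2 were recovered in 25% and 92% of 100 genes each, with 1 false call among 11346 unchanged genes (11136 of all simulated genes passed the filter). The count fell to 642 without 3′ replicate 1, to 416 without modified 5′ replicate 1, to 490 without modified 5′ replicate 2 and to 875 with every library thinned to 365826 counts. In B-like cells it was 1350 without 3′ replicate 1 and 1548 without modified 5′ replicate 2, and in T-like cells 689 and 764. Cd74 did not pass without modified 5′ replicate 2, nor Malat1 without 3′ replicate 1, modified 5′ replicate 1 or modified 5′ replicate 2.

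The third comparison asked what the added dNTP and longer extension changed, and no gene passed over all cells in edgeR's test without a block, while 21 passed, 9 higher and 12 lower in modified 5′, with the replicate number as a block. Rps21 (chr 2: 180257377 to 180258445), a small-subunit ribosomal protein gene, measured 1057 and 1726 CPM in standard 5′ and 5096 and 2887 CPM in modified 5′, a log2 difference of 1.52 ± 0.34 (± SE, 2 libraries per group). AY036118 (chr 17: 39847113 to 39848035; lincRNA) measured 191 and 230.4 CPM and 1044 and 446 CPM (1.81 ± 0.36). Within B-like cells 8 genes passed, 7 higher and 1 lower in modified 5′, and within T-like cells 4 passed, 2 higher and 2 lower. With the block these were 7 genes, 4 higher and 3 lower, with 5 of the 8 among them, and 4 genes, 3 higher and 1 lower, with 3 of the 4 among them. Of 11546 genes tested over all cells, 459 had an unadjusted p under 0.05, edgeR called 0 without the block and DESeq2 called 1, AY036118.

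Among the 10 genes with the smallest p, none of which passed without the block (edgeR adjusted p = 0.996), were also Atl1 (2.36 ± 0.50, chr 12: 69892614 to 69966417), which encodes a membrane-shaping GTPase, Bola2 (1.21 ± 0.28, chr 7: 126695401 to 126699798), which acts in iron handling, Rps15 (1.08 ± 0.26, chr 10: 80292453 to 80294114) and Hnrnpa0 (1.21 ± 0.30). Iglc1 (chr 16: 19061618 to 19062071), a lambda light chain constant gene, measured 5223 and 2533 CPM in standard 5′ and 1157 and 872 CPM in modified 5′ (-1.93 ± 0.48). The neutrophil genes S100a8 (3.57 ± 0.68), S100a9 (2.69 ± 0.61) and Camp were in the same group. Camp measured 3.07 and 0 CPM in standard 5′ and 15.7 and 38.1 CPM in modified 5′. Within replicates 1 and 2, the log2 differences were 2.27 and 0.74 for Rps21 and 2.45 and 0.95 for AY036118. With the block, Rps21 (log2 fold change 1.45, edgeR adjusted p = 0.00175), AY036118 (1.66), Rps15 (1.06), Bola2 (1.10), Camp (5.89), S100a8 (3.62), S100a9 (2.83), Ngp (6.55), another neutrophil granule gene, and Igha (3.64) rose. Iglc1 (-1.83) and the erythroid genes Klf1 (-2.03) and Alas2 (-1.55) fell.

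In B-like cells, AY036118 rose by 1.90 ± 0.29 (edgeR adjusted p = 1.5e-04), Rps21 by 1.48 ± 0.25 (edgeR adjusted p = 8.7e-04), and Bola2 by 1.27 ± 0.27. Tomm7 (1.27 ± 0.27, chr 5: 23838944 to 23844161), a gene of the mitochondrial outer membrane import complex, and Uqcr11 (1.26 ± 0.27, chr 10: 80402997 to 80406830), of respiratory complex III, rose as well. The other 3 of the 8 were Rps15 (1.12), Iglc1 (-1.45) and Atl1. In T-like cells Rps21 (1.56 ± 0.27) and AY036118 (1.59 ± 0.29) rose, and Cd160 (-2.30 ± 0.41, chr 3: 96798763 to 96829351) and Klra7 (-4.15 ± 0.81, chr 6: 130218605 to 130233322), receptor genes of cytotoxic lymphocytes, fell. Klra7 measured 35.5 and 50.9 CPM in standard 5′ and 6.26 and 0 CPM in modified 5′ T-like cells. AY036118 did not pass in B-like or T-like cells without modified 5′ replicate 1, and Rps21 did not pass in either class without standard 5′ replicate 1, nor in B-like cells without modified 5′ replicate 1. Bola2, Tomm7 and Uqcr11 each passed in 4 of 10 alternatives in B-like cells, and did not pass with the replicate block (edgeR adjusted p = 0.0643, 0.0643 and 0.0667). Klra7 passed in 6 of 10 and not with the block (edgeR adjusted p = 0.0693), and Cd160 did not pass at Leiden resolution 1.0 or without modified 5′ replicate 2. Neither passed at resolution 1.0, where a cluster of 55 cells led by Cd160, Cd7, Cxcr6 and Xcl1 was T-like in standard 5′ replicate 2 and one of 110 cells led by Xcl1 and with Cxcr6 among its top 10 genes was unnamed in modified 5′ replicate 2.

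Although no single gene passed over all cells without the block, 9 of 24 lists did by camera, 3 upward and 6 downward in modified 5′. Genes of oxidative phosphorylation had a median log2 fold change of 0.33 (camera adjusted p = 3.7e-06, and adjusted p = 0.648 with an estimated correlation). Uqcr11 was at 1.22 ± 0.34, Atp5mpl at 1.00 ± 0.28 and Ndufs5 at 0.94 ± 0.27. Ribosomal protein genes had a median of 0.21 (camera adjusted p = 0.0075, and adjusted p = 0.648 with an estimated correlation), with Rps25 at 1.01 ± 0.26 and Rplp1 at 0.89 ± 0.24. The neutrophil list ranked upward too (camera adjusted p = 4.5e-07, and adjusted p = 0.648 with an estimated correlation), with 4 members passing when adjusted over the list alone. In that way 0 members of the other 8 lists passed. The cell cycle list had a median of -0.51 (camera adjusted p = 3.9e-05, and adjusted p = 0.80 with an estimated correlation), with Mcm6 at -0.63 ± 0.30. Heat shock proteins had a median of -0.51 (camera adjusted p = 6.1e-04, and adjusted p = 0.648 with an estimated correlation). Hspa8 was at -0.69 ± 0.31, with within-replicate differences of -1.46 and -0.09. Proteasome genes had a median of -0.24 (camera adjusted p = 7.1e-04, and adjusted p = 0.684 with an estimated correlation). Interferon-stimulated genes had a median of -0.25 (camera adjusted p = 0.0054, and adjusted p = 0.648 with an estimated correlation), with Irf7 at -0.81 ± 0.26. T cell markers had a median of -0.29 (camera adjusted p = 0.017, and adjusted p = 0.795 with an estimated correlation), and T-like cells were 29.7% of modified and 36.5% of standard 5′ cells. MHC class I genes had a median of -0.34 (camera adjusted p = 0.039, and adjusted p = 0.858 with an estimated correlation), with H2-Q4 at -0.48 ± 0.22. Among 10 immunoglobulin constant genes, 3 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.184). No member passed without the block in the remaining lists, whose camera adjusted p was 0.28 for B cell, 0.73 for NK cell and 0.73 for monocyte or macrophage markers. It was 0.931 for dendritic cell, 0.569 for plasma cell and 0.152 for erythroid markers (3.07e-08 with the replicate block), 0.507 for mitochondrially encoded mRNAs, 0.366 for nuclear noncoding RNAs and 0.73 for histones. For the rest it was 0.062 for immediate early genes, 0.898 for MHC class II, 0.104 for T cell receptor constant genes, 0.293 for splicing factors and 0.662 for the isoform list. Only the oxidative phosphorylation, neutrophil and proteasome lists of the 9 passed whichever library was left out. Without modified 5′ replicate 1, camera's adjusted p was 0.193 for MHC class I, 0.0643 for ribosomal protein, 0.182 for heat shock and 0.25 for interferon-stimulated genes. Without standard 5′ replicate 1 it was 0.313 for ribosomal protein genes and 0.713 for the cell cycle list, which then ranked upward. Without standard 5′ replicate 2 it was 0.559 for MHC class I genes and 0.247 for T cell markers, which had 0.0624 without modified 5′ replicate 2. The lowest values over the 6 libraries left out in turn were 0.00456 for MHC class I, 0.00687 for ribosomal protein, 8.54e-08 for heat shock, 1.28e-04 for interferon-stimulated and 2.34e-10 for cell cycle genes and 0.00833 for T cell markers. Of the 9 lists, 5 passed in the same direction in B-like cells, where cell cycle (0.661), ribosomal protein (0.103) and interferon-stimulated genes (0.138) did not. In T-like cells 5 passed, and MHC class I (0.112), T cell (0.634) and interferon-stimulated genes (0.434) did not. The neutrophil list was not tested in either class. The monocyte list had a median of -0.01 and a mean of 0.05, and the MHC class II list a median of -0.02 and a mean of 0.02.

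Simulated log2 changes of 1 and 2 between modified and standard 5′ were recovered in 21% and 88% of 100 genes each, with 0 false calls among 11346 unchanged genes (11136 of all simulated genes passed the filter). Without a filter on low counts 65 genes passed, 38 higher and 27 lower, and without modified 5′ replicate 2 there was 1 gene, Ighg3. The B-like count of 8 was 2 without 3′ replicate 1, 2 without 3′ replicate 2 and 43 without modified 5′ replicate 2. The T-like count of 4 lay between 9 and 54 when any 1 library was left out. At an unadjusted p under 0.05 there were 552 genes in B-like and 426 in T-like cells.

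More genes were seen per cell at 500 counts and per library at 365826 counts with 3′ than with either 5′ protocol. At 500 counts per cell, the median number of genes was 386 and 381 in the 3′ libraries, 334 and 347 in standard 5′, and 344 and 349 in modified 5′. In the same order, 1712, 1971, 153, 1520, 938 and 1840 cells reached that depth. Without thinning, the medians over kept cells were 453 and 378, 246 and 342, and 337 and 375. The standard 5′ mean was -11.2% relative to 3′ (340.5 ± 9.19 against 383.5 ± 3.54, mean ± SD, n = 2; within replicates -13.5% and -8.92%, exact permutation p = 0.33). The modified 5′ mean of 346.5 ± 3.54 was -9.65% relative to 3′ (n = 2; -10.9% and -8.40%, exact permutation p = 0.33) and 1.76% above standard 5′ (2.99% and 0.58%, exact permutation p = 0.67). That last difference was -0.144% without standard 5′ replicate 1 and 3.74% without standard 5′ replicate 2. With every library thinned to 365826 counts, 14091 and 14124 genes were found in 3′, 12756 and 12629 in standard 5′, and 12921 and 12819 in modified 5′. The differences were -10.0% for standard 5′ against 3′ (within replicates -9.47% and -10.6%), -8.77% for modified 5′ against 3′ (-8.30% and -9.24%) and 1.40% for modified against standard 5′ (1.29% and 1.50%), each with an exact two-sided permutation p of 0.33 (n = 2 per group). The last was 0.894% without standard 5′ replicate 2.

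**Figure D2:**
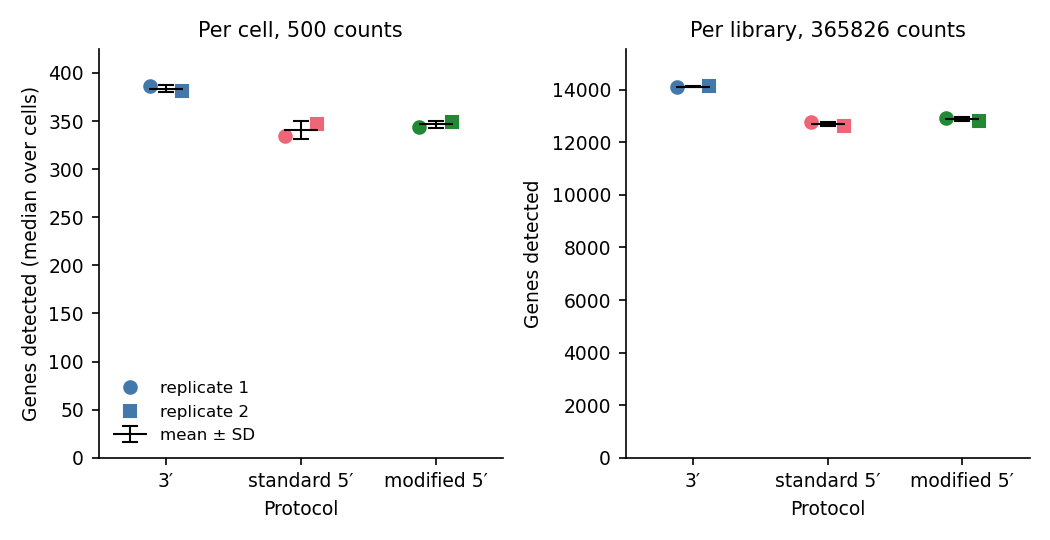
Genes detected per cell at 500 counts (median over cells) and per library at 365826 counts in the 3 protocols; circles are replicate 1, squares replicate 2, and bars the mean ± SD of 2 libraries. The 3′ libraries (386 and 381 genes per cell) lie above all 5′ libraries.

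Long genes were lower and genes of 501 to 2000 nt higher with either 5′ protocol than with 3′, by the length of the longest annotated transcript. Between standard 5′ and 3′ the median log2 fold change was 0.59 for 571 genes of 501 to 1000 nt, of which 163 rose and 31 fell. It was 0.65 for 1919 genes of 1001 to 2000 nt, of which 583 rose and 97 fell, and -0.59 for 1314 genes of 6001 to 10000 nt, of which 16 rose and 302 fell. For 287 longer genes it was -0.77, and 1 rose and 105 fell. The slope was -0.31 per doubling of length over 11412 genes (-0.28 and -0.27 within replicates). Spearman's rho across genes, which are not independent replicates, was -0.444 with length and 0.392 with GC content. Between modified 5′ and 3′ the medians of the same 4 classes were 0.64, 0.48, -0.48 and -0.72, with a slope of -0.28 (-0.29 and -0.21). Between modified and standard 5′ they were 0.06, -0.14, 0.12 and 0.12, with a slope of 0.03 (-0.01 and 0.06). The mean log2 length per count was 11.22 and 11.23 in 3′, 10.91 and 10.97 in standard 5′ and 10.91 and 10.99 in modified 5′. It differed by -0.28 for standard 5′ against 3′ (-0.31 and -0.25, exact permutation p = 0.33), -0.27 for modified 5′ against 3′ (-0.31 and -0.23, exact permutation p = 0.33) and 0.01 for modified against standard 5′ (0.00 and 0.02, exact permutation p = 0.67), with n = 2 libraries per group. The last lay between -0.03 (without modified 5′ replicate 2) and 0.05 (without modified 5′ replicate 1) when 1 library was left out. No test of single transcripts or isoforms could be run, because the counts used here are given per gene.

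**Figure D3:**
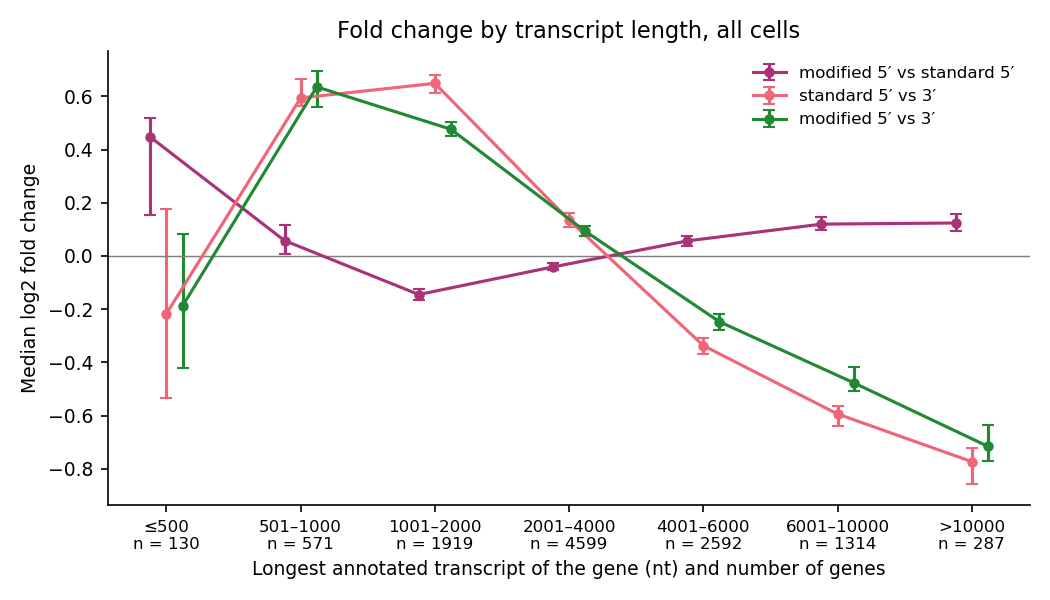
Median log2 fold change of genes in 7 classes of annotated transcript length (nt) for the 3 comparisons, with bootstrap 95% intervals over genes. The medians against 3′ fall from 0.65 (standard 5′, 1001 to 2000 nt) to -0.77 in genes above 10000 nt, while modified against standard 5′ lies between -0.14 and 0.45.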

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

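The difference between the effects in B-like and T-like cells and the 3 tests of the pancreatic hormone counts were chosen only after the data or the result had been seen.

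Pancreatic hormone and granule transcripts, which lie outside the comparisons above, appeared in modified 5′ replicate 2 alone, with 87 counts in 78 of its 3459 barcodes (2.26%): 57 of Ins2, 15 of Ins1, 6 of Gcg, 3 of Iapp and 2 each of Sst, Ppy and Chga. The other 5 libraries had 0 counts, where 3 counts would have been 1.14 to 4.15 CPM. The highest share of a barcode's counts was 0.348% for Gcg, Sst and Ppy together, which argues against captured cells that make mainly those hormones, and 1.364% for Ins1, Ins2 and Iapp, which leaves beta cells open because the labels say that insulin cDNA was depleted. Free or carried-over islet RNA may account for the counts, since B-like cells held 45.6 CPM and T-like cells 32.8 CPM, a ratio of 1.39 (95% interval 0.8 to 2.5) that leaves it open, with 46 of the 78 barcodes B-like, 17 T-like and a median depth of 507 counts. The labels name an islet protocol and this depletion for all 3 replicate 2 libraries, and no biological explanation was tested.

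A test of whether the effect of the protocol differed between B-like and T-like cells, with library as a term in edgeR, passed for 12 of 9280 genes between standard 5′ and 3′, 17 between modified 5′ and 3′ and 1 between modified and standard 5′ (463, 442 and 332 at an unadjusted p under 0.05). The genes include T cell genes with few counts in B-like cells: Trbc2 measured 1.16 to 81.0 CPM in B-like cells (0.0733% to 2.00% of cells with a count) against 2044 to 3917 CPM in T-like cells (61.6% to 80.4%), and Cd247 0 to 12.3 against 217 to 438 CPM. Cd74, the single gene between modified and standard 5′, measured 85.0 to 658 CPM in T-like and 14250 to 40120 CPM in B-like cells, at median depths of 303.5 to 690 and 342 to 540 counts per cell. Hbb-bs, a red cell transcript, measured 564.7 and 558 CPM in T-like and 2655 and 217 CPM in B-like cells of standard 5′ replicates 1 and 2, 5606 and 24.4 against 4931 and 303 CPM in modified 5′, and 530 and 10.15 against 3707 and 628 CPM in 3′. The order of the 2 classes thus turned between replicates in both 5′ protocols and not in 3′, where T-like cells were lower in both. Free RNA and doublets were not separated from expression, so counts of genes that are low in a class are not read as an effect of the protocol that differs by cell class. Nor are those of 3 genes chosen after their values were seen. 2010016I18Rik, a processed transcript, measured 217 and 173 CPM in T-like cells of 3′ against 68.5 and 52.6 in standard and 25.0 and 45.4 in modified 5′, and 27.9 to 65.5 CPM in B-like cells of the 6 libraries (differences between classes of -2.21 ± 0.35 and -1.79 ± 0.38 on the log2 scale against 3′, edgeR adjusted p = 5.9e-07 and 0.0021). Gm26917, a lincRNA, measured 1705 and 2668 CPM in B-like and 1966 and 3068 CPM in T-like cells of 3′, and 52.0 to 77.0 and 94.1 to 158 CPM in those of the 5′ libraries (0.94 ± 0.21 for modified 5′ against 3′, edgeR adjusted p = 0.0062, and 0.107 for standard 5′). Isg15, an interferon-stimulated gene, measured 50.8 to 97.2 CPM in B-like cells. In T-like cells it had 62.6 and 66.7 CPM in 3′ and 103 to 188.5 in 5′. It passed only for modified 5′ against 3′ (1.38 ± 0.31, edgeR adjusted p = 0.0062).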

How the results depend on the processing

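The values without haemoglobin genes, within B-like or T-like cells (except counts of changed genes and cell shares) and over all barcodes at 200 counts were chosen after the data were seen. Of 246 alternatives of counts and differences, 179 stayed within 1.5 times the main count or within 1 SD of the main difference and 67 moved. Of the genes that passed over all cells, 4 (standard 5′ against 3′, without standard 5′ replicate 2) and 3 in each comparison with 3′ (libraries thinned) changed sign, and without standard 5′ replicate 2 so did 55 in B-like and 22 in T-like cells. In the other class fits it was at most 3. Over all cells, the 152 gene and comparison pairs of the naming rule that passed gave 1971 alternative values, of which 1724 still passed, 247 did not and 0 turned. The 170 pairs that had not passed gave 2166, of which 172 passed. In B-like cells 228 of 250 and in T-like cells 232 of 240 values still passed, and 23 of 60 T-like values that had not passed did so. The cause was not tested unless stated. The alternatives chosen for transcripts were not run, because the counts are per gene.

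With DESeq2, 1 gene passed between modified and standard 5′, 1536 between standard 5′ and 3′ and 1226 between modified 5′ and 3′, and 1494 and 1193 of the last 2 counts were among edgeR's calls. Without a low-count filter 65 genes passed between modified and standard 5′. Thinning each library to the smallest total left 1230 and 875 genes against 3′, where depth is the setting that was lowered, and 1154 and 803 were among the main calls. The gene lists that passed fell to 0, 0 and 0 with an estimated correlation and to 0, 1 and 1 with fry (mitochondrially encoded mRNAs in both comparisons with 3′).

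With the replicate number as a block, 21 genes passed between modified and standard 5′, 4127 between standard 5′ and 3′ and 3820 between modified 5′ and 3′, with all 2689 and 2124 main calls among the last 2. The B-like counts were 7, 2966 and 2898, the T-like counts 4, 1855 and 1663, and 10, 13 and 12 lists passed. Of the B-like genes between modified and standard 5′, 4 were higher and 3 lower (7 and 1 without the block), and 5 of 8 calls were kept, and of the T-like genes 3 were higher and 1 lower (2 and 2), and 3 of 4 were kept.

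Leaving out each library in turn gave 0 to 1 genes between modified and standard 5′, 221 (without standard 5′ replicate 2) to 2763 between standard 5′ and 3′, with 966 without 3′ replicate 1, and 416 (without modified 5′ replicate 1) to 2216 between modified 5′ and 3′, with 642 without 3′ replicate 1 and 490 without modified 5′ replicate 2. In B-like cells the ranges were 2 to 43, 554 to 3096 and 1350 to 2922, and in T-like cells 9 to 54, 327 to 2050 and 689 to 1672.

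For genes per cell, modified against standard 5′, standard 5′ against 3′ and modified 5′ against 3′ differed by 16.93%, -24.63% and -11.88% at 1000 counts and by 5.171%, -23.74% and -19.79% at 2000. Standard 5′ replicate 1 had 413 genes in 47 cells at 1000 and 503 genes in 3 cells at 2000. Within replicates 1 and 2 the first 2 differences were 43.0% and -0.654%, and -38.5% and -11.0%, at 1000 counts. At 2000 all 3 were 22.7% and -3.26%, -45.3% and -5.82%, and -32.9% and -8.89% (exact permutation p = 1, 0.67 and 0.67), and 3′ replicate 1, with 920 genes, lay below standard 5′ (1044) and modified 5′ replicate 2 (1010). Over all deposited barcodes at 500 the first 2 were 29.25% (within replicates 83.6% and 0.576%) and -30.72% (-52.3% and -8.92%), with 183 genes in 253 barcodes of standard 5′ replicate 1, and over all barcodes at 200 the last 2 were -6.14% and -5.848%. B-like cells at 300 counts gave -8.871% and -8.266% against 3′, and T-like cells at 300 gave -1.092%, -5.761% and -6.79%.

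Genes per library against 3′ were -12.99% (standard) and -11.92% (modified) when detection needed 5 counts, -13.4% and -12.54% with the smallest total divided by 10, and -11.89% and -10.35% in B-like cells. Log2 length per count against 3′ was -0.1868 and -0.1896 with the median transcript length, -0.3372 and -0.3201 in B-like cells, and -0.3269 and -0.3259 there without mitochondrial, ribosomal protein and immunoglobulin genes. At Leiden resolution 1.0 the shares of modified 5′ against 3′ were -0.925 points for B-like and -2.665 points for T-like cells, where the main differences were positive.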

Other observations

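The test of the label of sex was chosen only after its values had been seen, and the tests of the cell mix, overlapping genes, shared ends and the trend with length were written before.

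Immunoglobulin transcripts were higher in B-like cells of standard 5′ than of 3′, where 6 of 8 tested constant region genes rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 1.22 (camera adjusted p = 0.037; an estimated correlation was not run within classes). Ighm rose by 1.57 ± 0.26, Igkc by 1.47 ± 0.22 and Iglc1 by 1.59 ± 0.31 (edgeR, 2 libraries per group). Igha, abundant in plasma cells, also passed (1.94 ± 0.48), on 5 and 18 counts in B-like cells of 3′ and 1 and 38 in standard 5′, in 0.247% to 1.25% of B-like cells over the 6 libraries, while over all cells it measured -3.31 ± 1.27 and did not pass (edgeR adjusted p = 0.0866; 1.55e-04 with the replicate block, and 1.77e-23 to 0.229 over the alternatives). In T-like cells, which do not make immunoglobulin, 3 of 5 tested members rose too, with a median of 1.23 (camera adjusted p = 0.0866). In modified 5′ against 3′, 4 of the 8 rose, with Igkc at 0.77 ± 0.22 and Iglc3 at 1.20 ± 0.23. In T-like cells, 6 of 7 T cell receptor constant genes rose between 3′ and standard 5′, over all genes and adjusted over the list alone, with a median of 1.75 (camera adjusted p = 6.6e-04). The 7 NK cell genes tested there had a median of -0.83 in modified against standard 5′ (camera adjusted p = 8.4e-04), and 0 passed over all genes while 4 fell adjusted over the list alone. NK-like cells of modified 5′ replicate 2 were 6.18% of cells at Leiden resolution 0.5 and 3.25% at 1.0, against 3.18% and 3.24% in standard 5′ replicate 2, so which cells stand as NK-like depends on the resolution.

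Some transcripts stood out in a single library or gene family. Ighg3 measured 1287 CPM in modified 5′ replicate 1, and Igha measured 279 and 169 CPM in 3′, 3.07 and 30.5 CPM in standard 5′ and 12 and 597 CPM in modified 5′. Counts of 556 olfactory and vomeronasal receptor genes took 0.958% and 0.746% of kept counts in 3′, 0.292% and 0.251% in standard 5′ and 0.322% and 0.320% in modified 5′. Ribosomal protein genes took 12.1% in both 3′ libraries, 15.1% and 16.5% in standard 5′ and 17.9% and 17.5% in modified 5′. Haemoglobin took 3.92% to 6.84% of kept counts in the replicate 1 libraries and 0.039% to 0.128% in the replicate 2 libraries.

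Xist, the RNA that silences an X chromosome in female cells, and its antisense partner Tsix were far higher in replicate 1 than in replicate 2 of each protocol, with counts that are uncertain between them where strand use is not stated. Xist measured 512 and 9.90 CPM in 3′, 85.7 and 0.493 CPM in standard 5′ and 118 and 4.63 CPM in modified 5′, and Tsix 565, 223 and 271 CPM in the replicate 1 libraries and 0 counts in the others. A different mix of cell types is argued against. In B-like cells alone the ratio of replicate 1 to replicate 2 was at least 140.3, with fewer than 3 counts set to 3. Another way of counting overlapping genes was tested on 126 genes overlapped over more of their exons than Xist (12.6%) and Tsix (32.6%). Their median log2 ratio of replicate 2 to replicate 1 differed from that of other genes by at most 0.25. Xist and Tsix lie outside that class, so the test cannot decide the question for them. Replicate 2 animals that were not female stay open as a cause. Xist and Tsix together were at 0.92%, 0.48% (1 count set to 3) and 1.19% of replicate 1. Of 12 pairs of escape gene and protocol, 9 were lower in replicate 2 where at least 10 had been asked for. Ftx, a neighbour of Xist, measured 308 and 267, 78.8 and 82.9, and 77.0 and 90.7 CPM over all barcodes, and no biological explanation was tested.

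Among the genes that passed, 118 were at least 4-fold higher and 269 at least 4-fold lower in standard 5′ than in 3′. A 3′ end shared with another gene, which could cost counts in 3′ libraries, was found for 15.5% of the higher genes (18 of 116; 95% interval 9.5% to 23.4%) against 7.4% of 4633 genes changed by little, so it is argued against as the main cause, as is a shared 5′ end for the lower genes (12.9%, 34 of 264, 9.1% to 17.5%; 8.4% of the others). A linear trend of log2 change with length and GC content was removed. Medians were then 1.98 (from 2.36, 95% interval 1.88 to 2.14) for the higher and -2.34 (from -2.55, -2.48 to -2.23) for the lower genes. Genes chosen for large folds cannot decide on that trend. What sets them apart stays open, and no biological explanation was tested.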
